A study of Mus musculus with 4 samples.

How the data were processed

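Per the labels, gene expression was measured in mouse lung RNA on Agilent 1-colour (Cy3) whole-genome arrays. They give 4 groups: wild type and Pla2g3 knockout, each as control and after antigen challenge. Each group had 1 array, hybridised with RNA pooled from 4 samples, and 200 ng of RNA was labelled. Challenged mice were sensitised with ovalbumin in alum (10 µg and 1.3 mg) on days 0 and 14, and inhaled 1% ovalbumin aerosol for 30 min per day on days 26, 27 and 28. Lungs were taken 48 h after the last challenge. The labels attach the same protocol to all samples, so what the controls received is not given in the sources used here. Groups were taken from the sample titles.

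The values came from 2 sources. Per the file headers, the scanner files hold spot intensity from Agilent Feature Extraction 11.5.1.1, with trends across the slide removed and no normalization between arrays. The background correction setting in the headers was 0 on all 4 arrays. Negative control spots had a median processed signal of 1.90 to 2.62. Probe coordinates in them are on mm9. The authors' value table holds a linear signal per probe and sample. How it was made is not given in the sources used here. Its values show that the 75th percentile of each column lies at about 1.00 and that genes were not centred. The plan had treated the table as another version of the scanner values, to be run as an alternative. Its columns did not follow the scanner files of the same names, or any other order of them, so every comparison is given for each source, and values were normalised and tested only within a source. This choice was made after the data were seen. No other column of sample values was found (0 columns).

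Each array had 44397 spots, of which 43020 were not controls and 153 were negative controls. The 39429 different probes were named from the gene reference supplied with the data: 28741 by transcript accession and 2037 by symbol, and 8651 kept the name given in the files. In this step 1660 probes received a newer symbol. The probes covered 30974 genes, and each gene was represented by its probe with the highest mean log2 signal over the 4 arrays of a source. This was the same probe in both sources for 30317 of 30966 genes. In the scanner files 19 probes marked as uneven on an array were left out, and no spot was saturated.

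Scanner intensities were taken to log2 and the 75th percentile of the array's non-control probes was subtracted. Table signals were taken to log2 with nothing subtracted, since the 75th percentile of each column already lay at about 1.00. A scanner probe counted as above background by Agilent's own flag. The table has no flag, so a probe counted as above background when it exceeded 5 times the median of the column's negative controls. Applied to the scanner files, this rule gave the same call as Agilent's flag for 99.2% of spots on each array. Genes above background on at least 1 array numbered 26244 in the scanner files and 25937 in the table. The error printed beside a scanner value is Agilent's own error of the spots, which covers the reading of the spots and not the variation between mice. The table gives no error. For arrays, precision is limited by their number, here 1 per group.

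The comparisons were challenged against control in each genotype, knockout against wild type in each treatment, and the difference of the challenge responses. With 1 array per group these have no p-value. A gene was counted as different at 2-fold or more, if above background on at least 1 of the arrays compared. The challenge effect averaged over genotypes and the genotype effect averaged over treatments were fitted with limma 3.58.1 (lmFit and eBayes in R 4.3.3) as an additive model, which leaves 1 residual degree of freedom per gene. P-values were adjusted by Benjamini-Hochberg over all genes above background, with a threshold of 0.05. The spread in this fit is the disagreement between the genotypes or treatments. It mixes any true interaction with differences between the pools, and does not measure the variation between mice of a group by itself. Correlations between responses are across genes, which are not independent replicates.

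There were 33 gene lists, for which the median log2 difference of the measured members was placed among 10000 random lists of the same size drawn from 10 bins of mean expression. Of the 93 list medians described, 90 lay outside the central 95% of the random lists, and the other 3 were of the phospholipase A2 and lysophospholipid lists. Which lists are described was chosen after the values were seen, as were 5 further marker lists written for the closing section (cartilage, airway basal and squamous epithelium, thyroid and parathyroid, thymic epithelium, and immature thymocytes). The genes named are Pla2g3, the 12 highest and 12 lowest by averaged challenge effect, the 10 highest and 10 lowest by KO-labelled minus WT-labelled array in each treatment, the 8 highest and 8 lowest by difference of responses, and up to 4 members per list. Fewer than 12 genes passed the limma threshold, so the challenge genes were taken by size alone. Ranked genes were above background on every array used. Up to 3 genes per direction that were above background on 1 side only are given apart, as lower bounds of their fold. Other genes with an array at background are given as bounds, with that array at the floor, and without a value where the higher side was at background. Clone, accession and predicted names and antigen receptor segments were not ranked. Any other gene named was chosen after its values were seen.

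Alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, scaling to the median of probes above background on all 4 arrays, the other source, a filter requiring all 4 arrays, no filter, the mean of a gene's probes, 1.5- and 3-fold rules, a rule adding 3 times the spot error, and limma with a variance trend, with robust eBayes, or with a 2-fold rule added. Alternatives on the value table, the 2-fold counts of averaged effects, the agreement of the genotype differences and the counts shared by both sources were chosen after the data were seen. No array could be left out, since each group has 1.

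The limma step was tested on simulated data with the spread fitted on the real arrays, for the averaged challenge effect. Of 50 changed genes per size among 26244 scanner genes, 0, 0, 31 and 47 passed at 2-, 4-, 16- and 64-fold, with 2 false calls. Among 25937 table genes the numbers were 0, 0, 38 and 43, with 1 false call. In 1 pair of simulated arrays, 1233 of 26044 unchanged scanner genes and 862 of 25737 unchanged table genes exceeded 2-fold, and 0 in either source with a small spread. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and matplotlib 3.10.9.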

Results

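Per the labels, RNA from mouse lung was measured on 4 arrays, each with RNA pooled from 4 samples. There was 1 for each labelled combination of genotype (wild type or Pla2g3 knockout) and treatment (control or antigen-challenged). The challenge was inhaled ovalbumin after sensitisation, a model of allergic asthma. Pla2g3 encodes a secreted phospholipase A2. The design asks how the lung responds to antigen and whether deletion of Pla2g3 alters that response or the unchallenged lung. There were no replicate arrays. In the scanner files, the intensity at the 75th percentile was 1986 for the control array labelled wild type (WT-labelled), 1834 for the control labelled knockout (KO-labelled), 1808 for the WT-labelled challenged array and 1979 for the KO-labelled one. The share of spots well above background was 81.3%, 80.8%, 81.9% and 79.2% in the same order. In the authors' value table, 82.1%, 80.3%, 81.8% and 79.8% of probes were above background. All 4 scanner arrays came from 1 slide and 1 scan, so neither separated the groups.

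The 2 sources did not hold the same measurements under the same sample names. Across probes, log2 levels of a scanner array and the table column of the same name correlated at 0.911 to 0.919, while the arrays within a source correlated at 0.985 or more. Repeated spots of a probe deviated from their mean in a similar way in both sources, but no more so under the same name (correlations of 0.332 to 0.567) than under different names (0.339 to 0.557). Most genes of the lung's air sacs, vessels and connective tissue were lower in the scanner files than in the table. The median difference was -3.68 on the log2 scale for 20 alveolar epithelial genes, -6.18 for 17 endothelial genes, -3.80 for 19 smooth muscle and matrix genes and -5.28 for 19 heart muscle genes. Sftpc, the surfactant protein of alveolar type II cells, had a mean log2 level of -0.74 in the scanner files and 6.99 in the table. Ager, a marker of alveolar type I cells, had -5.09 and 3.66. Of the 20 alveolar genes 4 were higher in the scanner files: Aqp5 (1.27), Lyz1 (0.93), Pdpn (0.87) and Sftpd (0.63). Genes of the conducting airways lay the other way, with medians of 2.13 for 19 ciliated cell genes and 1.31 for 15 club cell genes. Foxj1, a regulator of motile cilia, had 3.41 in the scanner files and 1.11 in the table. These levels compare sources normalised separately. Each comparison is therefore given first in the table and then in the scanner files.

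Pla2g3, the targeted gene, was higher in the arrays labelled knockout in both sources and both treatments. The array has 2 probes for it on chromosome 11 (mm9). The probe used for the gene lies at 3394109 to 3394168, at position 2562 of the transcript. In the table its log2 signal was -4.66 in the WT-labelled control, -0.20 in the KO-labelled control, -4.60 in the WT-labelled challenged array and 0.06 in the KO-labelled one, so it was 22.1-fold higher in controls and 25.4-fold higher after challenge. In the scanner files the levels were -3.05, 0.14, -2.83 and 1.07, a difference of 3.19 with a spot error of 0.20 in controls (9.14-fold) and of 3.90 with an error of 0.20 after challenge (14.9-fold). The other probe, at 3393127 to 3393186 and position 1580, was 16.2-fold and 14.8-fold higher in the table and 4.35-fold and 23.5-fold higher in the scanner files. The part of the gene that was deleted is not given in the sources used here, and a probe outside it does not check the labels. Arrays are therefore called KO-labelled and WT-labelled throughout, and every direction between genotypes rests on those labels.

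**Figure D1:**
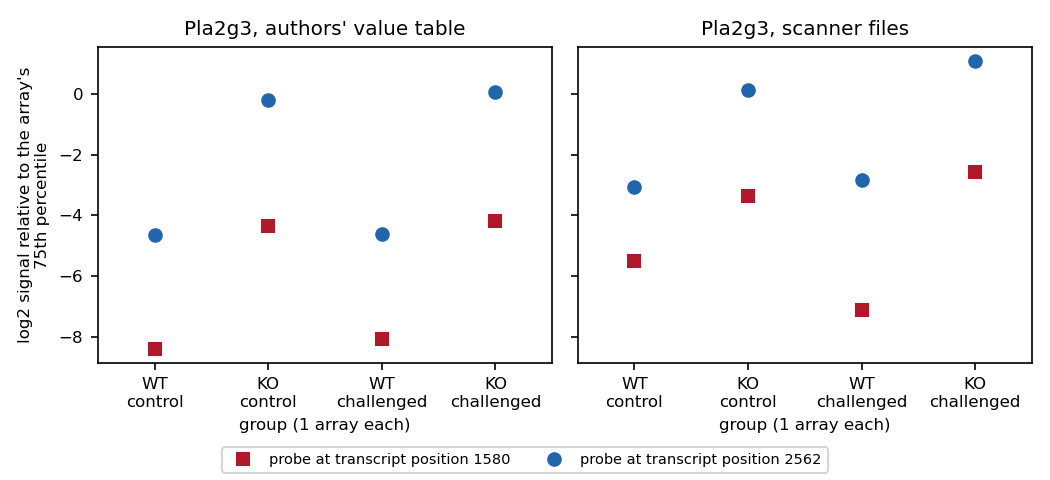
Log2 signal of the 2 Pla2g3 probes relative to the 75th percentile of each array, for the 4 groups (1 array each, no error bars), in the authors' value table and in the scanner files. Both probes were higher in the KO-labelled than in the WT-labelled array of the same treatment, for example -0.20 against -4.66 in the controls of the table for the probe at position 2562.

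The first comparison asks which genes respond to antigen. In the table, mucus, chemokine and alternatively activated macrophage genes were higher in both challenged arrays than in their controls. The highest averages over genotypes were those of Tff1, a secreted peptide of mucous epithelia (4.36 on the log2 scale, 20.5-fold), the eosinophil-attracting chemokine Ccl24 (4.15, 17.8-fold), Retnlb, a goblet cell product (4.13, 17.5-fold), the protease Capn9 (3.95, 15.4-fold) and the airway mucin Muc5ac (3.81, 14.0-fold). Ccl24 was 3.13 higher in the WT-labelled pair and 5.17 higher in the KO-labelled pair. They were followed by the lectin receptor Cd209e (3.48), the lectin Itln1 (3.34), Fbp1, an enzyme of gluconeogenesis (3.10), the actin-severing protein Scin (3.05), the cytosolic phospholipase A2 Pla2g4c (2.98), the chemokine Ccl1 (2.98) and the mucus protein Fcgbp (2.80). Genes above background only in challenged arrays were Tmprss11c (at least 5.84-fold higher), Epo (at least 4.65-fold) and Serpinb11 (at least 3.98-fold).

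By list, 13 of 20 mucus and goblet cell genes were at least 2-fold higher in the table and none was lower (median 1.41). Their median was 1.26 in the WT-labelled and 1.59 in the KO-labelled pair. Among 20 chemokines and their receptors, 9 were at least 2-fold higher (median 0.89), including Ccl8 (2.49) and Ccl17 (1.96), ligands of Th2 cell receptors. Of 15 alternatively activated macrophage genes 5 were (median 0.49), including the chitinase-like Chil4 (2.30), the arginine-degrading enzyme Arg1 (1.58) and Pdcd1lg2 (1.46). Among 18 type 2 cytokines, alarmins and receptors, Il13 (1.87), Il21 (at least 1.44), the interleukin 33 receptor Il1rl1 (1.12) and Il9r (1.06) were (median 0.36). Of 15 eosinophil genes 4 were (median 0.52): Alox15 (2.33), Cebpe (1.86), the granule protein Prg2 (1.32) and the eosinophil peroxidase Epx, which was at background in both WT-labelled arrays. Prg2 had close levels in the WT-labelled control (-2.09) and challenged (-2.10) arrays. Its average rests on the KO-labelled pair, whose control was low (-4.54). Acute phase and complement genes had a median of 0.66, with Saa3 at 2.31 and Saa1 at 1.71, and dendritic cell genes one of 0.51. All 30 cell cycle genes were above 0 (median 0.83, or 0.81 with arrays at background set to the floor). Of these 4 were above background on all arrays and at least 2-fold higher, such as Mki67 (1.06). Genes of NK and cytotoxic cells were lower by less than 2-fold (median of 14, -0.40), for example Ncr1 (-0.63) and Cd160 (-0.52), and 20 endothelial genes had a median of -0.14. Each of these medians lay outside the central 95% of random lists matched on expression.

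Fewer genes were lower after challenge in the table. The lowest averages were the sulfotransferase Sult2a1 (-2.17, 4.5-fold), the neutrophil chemokine receptor Cxcr1 (-1.77), the xenobiotic-metabolising enzyme Cyp1a1 (-1.76), Sult2a6 (-1.69), the brown fat uncoupling protein Ucp1 (-1.59), the fatty acid-binding protein Fabp1 (-1.47), Spag11b (-1.37), the hepatic lectin Asgr1 (-1.27), Slc6a12 (-1.26), the muscle receptor subunit Chrng (-1.24), Vmn1r59 (-1.19) and Spon2 (-1.14). Cyp1a1 was -4.30 in the WT-labelled pair and 0.77 in the KO-labelled pair, Cxcr1 was -0.16 and -3.39, Ucp1 -0.20 and -2.99, Slc6a12 -0.19 and -2.34, and Chrng -0.12 and -2.36, so their averages rest on 1 genotype. Genes above background only in controls were Dcst1 (at least 2.94-fold lower), Slc12a1 (at least 2.33-fold) and Olfr394 (at least 2.25-fold).

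In the table, 885 of 25555 genes were at least 2-fold different in the WT-labelled pair (604 higher, 281 lower) and 1160 of 24977 in the KO-labelled pair (820 higher, 340 lower). The averaged effect reached 2-fold for 848 genes (587 higher, 261 lower). In limma's additive fit 0 of 25937 genes passed an adjusted p of 0.05. The lowest was 0.476 (Retnlb), and 2274 genes had an unadjusted p under 0.05 against 1297 by chance. With a variance trend in limma, 118 genes passed (100 higher, 18 lower), the lowest adjusted p being 0.00119 (Capn9), and 13 of the 24 ranked genes were among them. When adjusted over the list alone, 14 mucus, 8 chemokine, 10 macrophage, 2 type 2, 13 acute phase, 10 dendritic, 6 NK and 0 eosinophil or cell cycle genes passed, and 0 over all genes. The lists described were chosen after their values in these same arrays were seen, and this adjustment does not cover that choice. Counts within a list are therefore conditional on it and are not separate evidence of a response. Simulated pairs of unchanged arrays gave 862 genes over 2-fold with the fitted spread, which contains any true difference between the genotypes, and 0 with a small spread, so they do not tell how many of the counted genes differ by noise.

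Neutrophil, chemokine and acute phase genes were higher in the challenged arrays of the scanner files, and T cell genes lower. Cxcl5, a neutrophil-attracting chemokine of epithelial cells, had the highest average (6.75, spot error 0.14, 108-fold), followed by the anion exchanger Slc26a4 (4.41, 21.2-fold), Slfn4 (3.90), the itaconate-forming enzyme Acod1 (3.88), Mirt2 (3.83), Cstdc4 (3.72), the potassium channel Kcnj15 (3.64), the iron-binding Lcn2 (3.62), Saa3 (3.60), Ccl17 (3.57), the monocyte chemokine Ccl7 (3.56) and Pla2g4c (3.49). Spot errors of the ranked genes ran from 0.14 to 0.20. The Th2 cytokines Il5 (at least 15.9-fold higher) and Il13 (at least 11-fold) and Faiml (at least 8.97-fold) were above background only after challenge. The lowest were the parathyroid hormone gene Pth (-3.29, 9.77-fold), H2-T3 (-2.90), the T cell factor Lef1 (-2.47), the adaptor Sh2d1a (-2.43), the pre-T cell receptor chain Ptcra (-2.33), Tmem151b (-2.32), Endou (-2.31), the T cell co-receptor chains Cd8a (-2.29) and Cd8b1 (-2.27), the recombinase Rag1 (-2.26), Cd3d (-2.25) and the T cell regulator Bcl11b (-2.24). Apart from Pth, these averages rest mostly on the KO-labelled pair, and those of Ptcra (0.085 in the WT-labelled and -4.75 in the KO-labelled pair), Endou (0.047 and -4.66) and Tmem151b (-0.38 and -4.26) almost wholly on it. Fnd3c2 (at least 4.86-fold lower), Defb9 (at least 4.02-fold) and Olfr352 (at least 3.49-fold) were above background only in controls.

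By list, 11 of 19 neutrophil genes were at least 2-fold higher in the scanner files (median 2.09), with Lcn2, Il1b (3.42), the collagenase Mmp8 (2.68) and Cxcr2 (2.66) at the top. Of 20 chemokines and receptors 11 were (median 1.69, or 1.05 with arrays at background set to the floor), including Ccl1 (at least 5.09) and Cxcl2 (at least 3.81). Their median was 0.55 in the WT-labelled and 2.71 in the KO-labelled pair (2.25 with the floor). Of 20 acute phase and complement genes 12 were (median 1.5, or 1.14 with the floor), among them Serpina3n (3.01) and Il6 (at least 2.63). Mucus genes had a median of 0.60, with Tff1 at 2.32, Clca1 at 1.26 and Muc5ac at 1.00. Of 30 interferon response genes 5 were at least 2-fold higher (median 0.63), led by Cxcl10 (3.09) and Cxcl9 (1.85). In the type 2 list (median 0.26), 5 of 19 were, including Il13, Il5, Il4 (1.28) and Il9, which was above background on 1 array, and 1 was lower. Endothelial genes had a median of 0.45. T cell genes were at least 2-fold lower for 13 of 21 (median -1.57) and thymocyte genes for 11 of 12 (median -2.02). The thymocyte medians were -0.48 in the WT-labelled and -3.42 in the KO-labelled pair, whose control array had the highest level of these genes. The cell cycle list, with a median of -0.38, lay opposite to its direction in the table. All these medians lay outside the central 95% of matched random lists.

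Of 25757 genes in the scanner files, 1145 were at least 2-fold different in the WT-labelled pair (621 higher, 524 lower), 2221 of 25413 in the KO-labelled pair (1115 higher, 1106 lower), and 1366 on average (745 higher, 621 lower). With normexp background correction these counts were 190, 715 and 349. In limma's additive fit 0 of 26244 genes passed, with a lowest adjusted p of 0.513 (Cxcl5) and 2513 genes at an unadjusted p under 0.05 against 1312 by chance. Cxcl5 alone passed in limma with a variance trend (adjusted p 0.0223) and with normexp (adjusted p 0.0237). When adjusted over the list alone, 9 neutrophil, 4 chemokine, 9 acute phase, 5 mucus, 7 interferon and 0 T cell genes passed. These counts too are conditional on lists chosen after their values were seen, and are not separate evidence of a response. Simulated unchanged pairs gave 1233 genes over 2-fold with the fitted spread and 0 with a small spread.

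**Figure D2:**
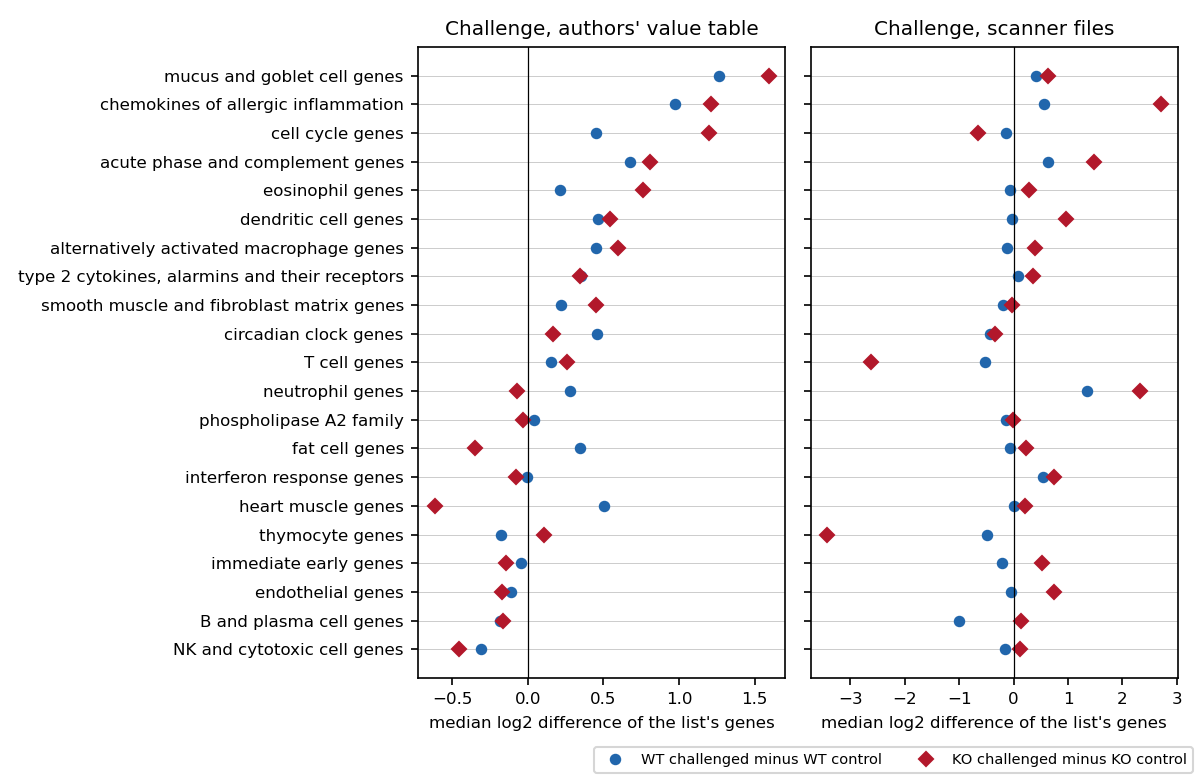
Median log2 difference, challenged minus control, of gene lists in the WT-labelled pair (circles) and the KO-labelled pair (diamonds), in the authors' value table and in the scanner files (1 array per group, so no error bars, and the x axes differ). Mucus genes had medians of 1.26 and 1.59 in the table, and the chemokine list had 0.55 and 2.71 in the scanner files (2.25 for the latter with arrays at background set to the floor).

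Genes at least 2-fold different in the same direction in both genotypes of both sources numbered 20 of 19043 symbols, 19 higher and 1 lower. The higher ones included Retnlb (average at least 3.15 in the scanner files and 4.13 in the table), Tff1 (2.32 and 4.36), Pla2g4c (3.49 and 2.98), Il13 (at least 3.45, and 1.87), Ccl1 (at least 5.09, and 2.98), Ccl17 (3.57 and 1.96), Slc26a4 (4.41 and 1.78), Saa3 (3.60 and 2.31), Saa1 (2.37 and 1.71), Scin (1.46 and 3.05), the chitinase-like Chil5 (3.08 and 1.22), the lipoxygenase Alox12e (2.29 and 2.0), the adrenergic receptor Adra2a (1.83 and 2.12) and the keratin Krt76 (at least 2.25 and at least 1.87). The lower one was Sult2a4 (lower by at least 1.55 and at least 1.70). Of the 20 genes 15 were above background on all 4 scanner arrays and in all 4 table columns. All 20 passed 2-fold in each pair when values at background were set to the floor. On average over genotypes, 56 genes were at least 2-fold higher in both sources against 6.13 for independent lists, 9 were lower in both against 1.97, and 29 went opposite ways against 7.77. Across all genes the averaged responses of the sources correlated at 0.0948.

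The next comparison asks what differs between genotypes without challenge. In the table, T cell, dendritic cell and antibody-producing cell genes were lower in the KO-labelled control array, and the highest genes included a cluster of protease inhibitors. The highest were Gdpd3, a lysophospholipase D (6.03, 65.2-fold), Serpina1c (5.14, 35.4-fold), Serpina1a (5.0), Serpina1e (4.94), Serpina1d (4.57), Pla2g3 (4.46), the surface antigen Psca (4.43), Awat1, a wax-forming acyltransferase (4.33), the lens protein Cryaa (3.89) and Cxcr1 (3.59). The Serpina1 genes are near-identical alpha-1-antitrypsin copies whose probes can bind each other's transcripts, so they are not separate results. Trim12a, a member of a family of antiviral restriction factors, was lowest (-9.86, 928-fold), followed by Cyp1a1 (-4.66), the RNA-binding Samd4 (-4.58), the synaptotagmin Syt15 (-3.91), Tmem221 (-3.50), Unc93a2 (-3.34), the kinase Camk2b (-3.30), Oosp1 (-2.99), the primase subunit Prim2 (-2.92) and Ankrd63 (-2.90). Col6a4 (at least 26.4-fold higher), Bhmt2 (at least 24.7-fold) and Olfr554 (at least 14.5-fold) were above background only in the KO-labelled control, and Gdf2 (at least 11-fold lower), Ttll2 (at least 10.1-fold) and Apol7d (at least 8.98-fold) only in the WT-labelled control.

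Of 21 T cell genes in the table, 3 were at least 2-fold lower in the KO-labelled control and none higher (median -0.79), including the checkpoint receptor Pdcd1 (-1.91) and Foxp3, the regulator of regulatory T cells (-1.12). Of 15 dendritic cell genes 6 were lower (median -0.77), among them the Langerhans cell lectin Cd207 (-1.93), Ccl17 (-1.72) and Ccl22 (-1.58). B and plasma cell genes had a median of -0.56, with the immunoglobulin joining chain Jchain at -2.17 and Mzb1 at -1.55. Chemokines went both ways (3 higher, 7 lower, median -0.43), with Ccl1 at -2.64, Ccl8 at -1.82, Cxcl3 at 2.30 and Cxcl2 at 1.90. NK and cytotoxic cell genes had a median of 0.35 and cell cycle genes one of -0.37. In the same pair of arrays, heart muscle genes had a median of 0.81, with 7 of 20 at least 2-fold higher, for example Tnnc1 (1.65) and Myh7 (1.5), and fat cell genes one of 0.34. In all, 1311 of 25384 genes were at least 2-fold different (487 higher, 824 lower).

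Genes of developing and mature T cells were higher in the KO-labelled control array of the scanner files. The highest were the recombinase genes Rag1 (5.80, spot error 0.21, 55.6-fold) and Rag2 (5.44, 43.4-fold), Endou (5.66), the DNA polymerase Dntt of receptor rearrangement (5.60), Myl10 (4.99), H2-T3 (4.94), Sh2d1a (4.94), Ptcra (4.92), the adaptor Trat1 (4.42) and Tmem151b (4.42). All 12 thymocyte genes were at least 2-fold higher (median 4.09), as were 15 of 21 T cell genes (median 2.65), including Cd8a (4.29), Cd8b1 (4.08) and the kinase Lck (3.66). Cell cycle genes were higher with them, 19 of 30 by at least 2-fold (median 1.13, or 1.08 with 2 genes at their bound), for example Top2a (1.59). B and plasma cell genes were at least 2-fold lower for 8 of their members and higher for 2 (median -0.87), with the receptor Tnfrsf13c at -2.33 and Fcmr at -2.05. The 2 higher ones were Jchain (1.09, against -2.17 in the table) and Tnfrsf17, which was lower in the table. Mzb1 was lower in both sources (-0.70, and -1.55 in the table). Of the endothelial genes 7 were at least 2-fold lower (median -0.60), such as Tie1 (lower by at least 2.42) and Cldn5 (-1.44).

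The lowest in the KO-labelled control array of the scanner files were Slc26a4 (-3.54, 11.7-fold), Tmem221 (-3.04), Trim69 (-2.74), Serpina3n (-2.67), Unc93a2 (-2.48), Sema3g (-2.37), the growth factor Areg (-2.35), Tnfrsf13c (-2.33), Dcstamp (-2.26) and Mmrn2 (-2.14). Trim12a was above background only in the WT-labelled control (at least 158-fold lower), as were Zic2 (at least 8.54-fold) and Glycam1 (at least 8.47-fold). Spo11 (at least 17.6-fold higher), Art1 (at least 11-fold) and Vstm2a (at least 10.6-fold) were above background only in the KO-labelled control. In all, 1526 of 25555 genes were at least 2-fold different (917 higher, 609 lower), and 468 with normexp background correction (359 higher, 109 lower). T cell, cell cycle, thymocyte and endothelial medians had the opposite sign in the table, at -0.79, -0.37, -0.46 and 0.11.

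The genotypes were then compared after challenge. In the table, 656 genes were at least 2-fold different in the same direction as in controls, and 127 in the opposite direction. Gdpd3 was highest (5.61, 48.7-fold), followed by Serpina1d (4.70), Pla2g3 (4.66), Serpina1c (4.65), Serpina1a (4.42), Serpina1e (4.42), Psca (4.29), the pyrimidine-degrading enzyme Dpys (4.02), Cryaa (3.91) and Olfr215 (3.53). The lowest were Samd4 (-4.69, 25.8-fold), the nuclease Dnase1 (-3.53), Camk2b (-3.35), the glycosyltransferase B3gnt3 (-3.14), Syt15 (-3.11), the complement protease Masp2 (-2.95), Tmem221 (-2.92), Prim2 (-2.84), Serpina9 (-2.82) and Unc93a2 (-2.72). Trim12a (at least 872-fold lower), Rnase2b (at least 14.2-fold) and Ceacam18 (at least 13.9-fold) were above background only in the WT-labelled array, and Col6a4 (at least 26.3-fold higher), Usp17le (at least 15.2-fold) and Obox3 (at least 10.8-fold) only in the KO-labelled array.

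Among the lists in the challenged arrays of the table, 4 of 15 eosinophil genes were at least 2-fold higher in the KO-labelled array (median 0.30, upper end of the 95% range of random lists 0.14): Epx (at least 2.78), Cebpe (1.36), Alox15 (1.2) and Ear6 (1.05). Mucus genes had a median of 0.36, with Agr2 at 1.41 and Itln1 at 1.08, and cell cycle genes one of 0.35. T cell genes were lower by less than 2-fold (median -0.56), for example Trat1 (-0.92) and Icos (-0.90). Of the dendritic cell genes 4 were at least 2-fold lower (median -0.56), including Cd207 (-1.95) and the cross-presenting cell receptor Xcr1 (-1.36), as were 4 B and plasma cell genes (median -0.48), including Jchain (-2.22). The chemokine median was -0.29, with Ccl24 at 1.68 and Ccl17 at -1.17. Phospholipase A2 genes as a list had a median of 0.050, inside the range of matched random lists, with Pla2g4c at 1.83 and Pla2g4d at -2.33 beside Pla2g3. Eicosanoid genes had a median of 0.10, with the leukotriene receptor Cysltr2 at -1.83, and lysophospholipid genes one of 0.050, with the acyltransferase Lpcat2 at 1.76. In the same pair, heart muscle genes (median -0.36) and fat cell genes (median -0.36, or -0.22 with arrays at background set to the floor) were lower, with Ucp1 at -2.40. In all, 1471 of 25330 genes were at least 2-fold different (535 higher, 936 lower).

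Chemokine, neutrophil and type 2 cytokine genes were higher in the KO-labelled challenged array of the scanner files. The highest were the neutrophil-attracting chemokines Cxcl1 (4.47, spot error 0.21, 22.2-fold), Cxcl3 (3.93) and Cxcl2 (3.70), the cytokine Il17a (4.03, 16.4-fold), Pla2g3 (3.90), the scavenger receptor Olr1 (3.65), Mrgpra6 (3.49), Il1b (3.38), Acod1 (3.36) and Il1f9 (3.33). Of 20 chemokines and receptors 16 were at least 2-fold higher and none lower (median 1.83), including Ccl7 (2.99). So were 11 neutrophil genes (median 1.30), such as the formyl peptide receptor Fpr1 (2.75) and Cxcr2 (2.39). Of the type 2 list 7 were (median 0.83), among them Il9 (at least 2.67), Il13 (2.46), Il5 (2.40) and the alarmin Tslp (at least 2.14). Of 14 dendritic cell genes 5 were (median 0.86), including Ccl17 (2.90) and Ccl22 (at least 2.30), of acute phase genes 7 (median 0.76), including Il6 (3.01), and of 23 immediate early genes 4 (median 0.61), including Egr2 (2.60). T cell genes (median 0.93, 8 at least 2-fold higher), thymocyte genes (median 1.11, 7 of 12) and cell cycle genes (median 0.75, 0 at least 2-fold) were higher in the same array.

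The lowest in that pair were Slc26a4 (-3.97, 15.7-fold), the relaxin family receptor Rxfp3 (-3.30), Oxct2b (-3.16), the neuronal factor Neurod2 (-2.79), the defensin Defb26 (-2.67), Dnajb8 (-2.65), Gal3st2 (-2.59), Angptl7 (-2.58), the desmosomal cadherin Dsg1c (-2.53) and Kif12 (-2.38), with spot errors from 0.20 to 0.35. Trim12a (at least 103-fold lower), Wfdc6b (at least 8.85-fold) and Mbd3l2 (at least 8.30-fold) were above background only in the WT-labelled array, and Olfr968 (at least 11.1-fold higher), Fshr (at least 9.64-fold) and Fam131b (at least 7.47-fold) only in the KO-labelled array. In all, 2101 of 25686 genes were at least 2-fold different (1078 higher, 1023 lower), and 498 with normexp background correction (354 higher, 144 lower). In the table the chemokine, neutrophil, T cell and dendritic cell medians of this pair had the opposite sign, at -0.29, -0.062, -0.56 and -0.56, and Cxcl1 was at -0.042, Il17a at -1.53 and Slc26a4 at 0.62.

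Genotype differences of at least 2-fold in both treatments and the same direction in both sources were found for 17 of 19043 symbols, 7 higher and 10 lower in the KO-labelled arrays. The higher ones were Pla2g3 (average 3.55 in the scanner files and 4.56 in the table), Cryaa (1.41 and 3.90), Zfp963 (2.39 and 2.70), the adenylyl cyclase Adcy1 (at least 1.89, and 2.39), Ocel1 (1.69 and 2.16), Lpcat2, an enzyme that makes platelet-activating factor (1.74 and 1.77), and Calr3 (1.52 and 1.63). The lower ones were Trim12a (lower by at least 6.99 and at least 9.81) and its family member Trim34a (-1.40 and -2.60), Tmem221 (-2.33 and -3.21), Unc93a2 (-1.98 and -3.03), B3gnt3 (-1.67 and -2.98), Serpina9 (-1.73 and -2.80), Eddm3b (lower by at least 1.17 and at least 1.15), Tmem212 (-1.30 and -1.96), the anaphase regulator Pttg1 (-1.68 and -1.59) and the carboxylesterase Ces1b (-1.91 and -1.49). Adcy1, Trim12a and Eddm3b had arrays at background, the other 14 had none, and all 17 passed 2-fold in each pair with such values set to the floor. On average over treatments, 35 genes were at least 2-fold higher in both sources against 7.34 for independent lists, 47 were lower in both against 6.97, and 102 went opposite ways against 17.7.

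Averaged over treatments, 1266 genes of the table were at least 2-fold different between genotypes (453 higher, 813 lower). T cell genes had a median of -0.66, dendritic cell genes -0.73, B and plasma cell genes -0.56, chemokines -0.26, NK and cytotoxic cell genes 0.25, mucus genes 0.24 and ciliated cell genes 0.20. The phospholipase A2 list had a median of 0.073, and lysophospholipid genes had 0.098 and eicosanoid genes 0.078, the last with Cysltr2 at -1.98. In limma's additive fit 0 of 25937 genes passed, with a lowest adjusted p of 0.109 (Trim12a) and 3571 genes at an unadjusted p under 0.05 against 1297 by chance. With a variance trend in limma, 1047 genes passed (413 higher, 634 lower), Trim12a having the lowest adjusted p (2.19e-05), and 20 of the 26 genes ranked by genotype did. In limma restricted to genes above background on all 4 arrays, 270 passed (102 higher, 168 lower). Adjusted over the list alone, 17 T cell, 10 dendritic, 14 B and plasma, 6 NK, 2 mucus and 0 chemokine genes passed, and 0 over all genes. The counts within lists are conditional on lists chosen after their values were seen, and are not separate evidence of a genotype difference.

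Averaged over treatments in the scanner files, 1500 genes were at least 2-fold different between genotypes (917 higher, 583 lower), and 334 with normexp background correction (273 higher, 61 lower). In limma's additive fit 0 of 26244 genes passed, with a lowest adjusted p of 0.424 (C430049E01Rik) and 2813 genes at an unadjusted p under 0.05 against 1312 by chance, and 0 passed with a variance trend.

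**Figure D3:**
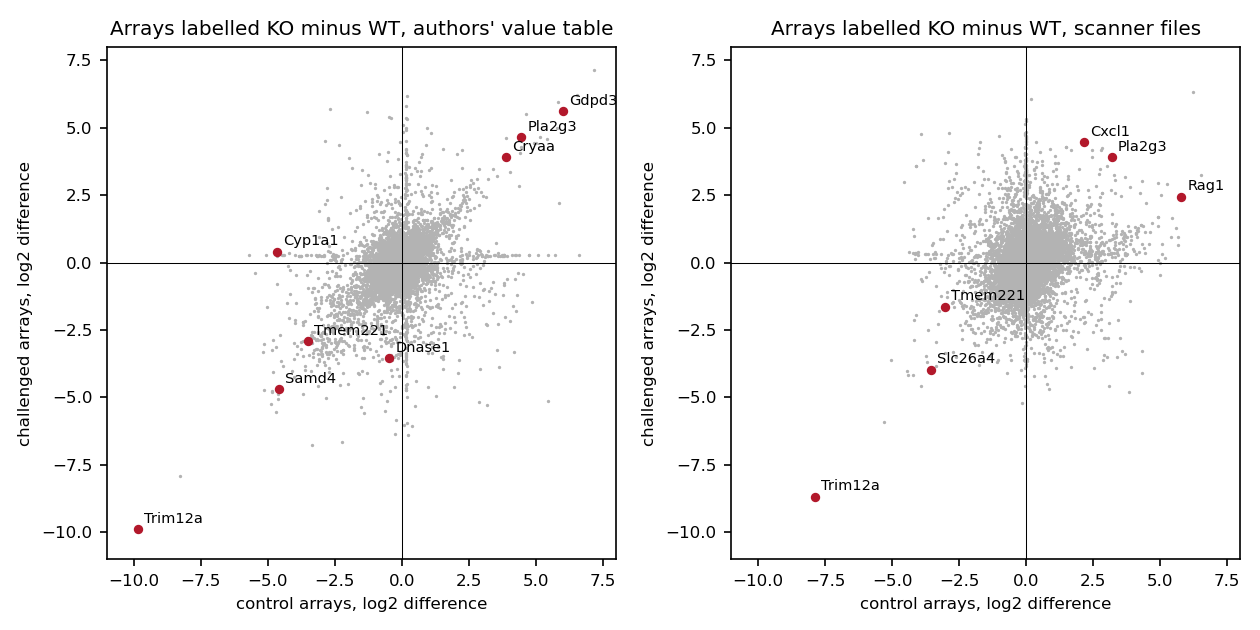
Log2 difference, KO-labelled minus WT-labelled, in the control arrays (x) and the challenged arrays (y) for each gene above background on at least 1 array (grey points), with some named genes in red, in the authors' value table and in the scanner files (1 array per group). Pla2g3 lies at 4.46 and 4.66 in the table and at 3.19 and 3.90 in the scanner files, and Trim12a lies at the lower left in both.

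The last comparison asks whether the response to antigen differs between genotypes. In the table, eosinophil and cell cycle genes had a higher response in the KO-labelled pair than in the WT-labelled pair. Of 15 eosinophil genes 5 had a response at least 2-fold higher in the KO-labelled pair (median difference 0.65), or 4 of the 14 above background on all arrays (median 0.57), led by Prg2 (2.68), Alox15 (1.60) and Cebpe (1.49). Prg2 itself had a response of -0.016 in the WT-labelled and 2.66 in the KO-labelled pair. Its levels after challenge were close (-2.10 and -1.87), and it was the controls that differed (-2.09 and -4.54). All 30 cell cycle genes had a higher response in the KO-labelled pair (median 0.67), with Ttk at 1.62 and Top2a at 1.07, from medians of 0.45 and 1.2 in the 2 pairs. Chemokine differences went both ways (4 higher, 4 lower, median 0.34), with Ccl1 at 2.72, Ccl24 at 2.04, Cxcl3 at -2.76 and Cxcl2 at -2.17. The neutrophil median was -0.40 and the smooth muscle and matrix median 0.27. Heart muscle genes (median -1.13, 11 of 20 at least 2-fold lower, such as Nppa at -1.96) and fat cell genes (median -0.90, or -0.69 with the floor, 6 lower) had the opposite difference.

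The 8 genes with the highest difference of responses in the table were Cyp1a1 (5.06, 33.5-fold), Dpys (3.28), Olfr215 (3.24), Ankrd53 (3.0), Ccl1 (2.72), Prg2 (2.68), Olfr59 (2.49) and the vitamin D-degrading enzyme Cyp24a1 (2.45). The 8 lowest were Awat1 (-4.73, 26.5-fold), the pluripotency-associated Dppa4 (-3.51), Cxcr1 (-3.23), Dnase1 (-3.05), Ucp1 (-2.79), Vmn2r10 (-2.78), Cd200r2 (-2.78) and Cxcl3 (-2.76). In all, 1569 of 25937 genes differed by at least 2-fold (783 higher, 786 lower), and 552 when a gene had to be above background on all 4 arrays. This difference has no test, since 1 array per group leaves no residual for it.

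In the scanner files, chemokine and B cell genes had a higher response and T cell genes a lower response in the KO-labelled pair. Serpina3n was highest (4.91, spot error 0.29, 30.1-fold), followed by Cxcl3 (4.36), Acod1 (4.09), Il17a (4.03), the macrophage receptors Marco (3.95) and Clec4e (3.80), Cd5l (3.79) and Pth (3.67). The lowest were Ptcra (-4.83, 28.5-fold), Endou (-4.71), Dntt (-4.33), Rxfp3 (-4.32), Oxct2b (-4.06), the cartilage collagen Col2a1 (-3.92), Tmem151b (-3.88) and Rag2 (-3.80), with spot errors up to 0.47. Of 20 chemokines and receptors 13 differed by at least 2-fold, all higher (median 1.81), including Ccl7 (2.85) and Ccl24 (2.72). Ccl24 was lower after challenge in the WT-labelled pair (-1.35) and higher in the KO-labelled pair (1.37), so that its average was 0.0068, against 4.15 in the table. B and plasma cell genes (median 1.15, 12 higher), dendritic cell genes (median 1.09, 7 higher), immediate early genes (median 0.81, 10 higher, Fosl1 at 2.35) and endothelial genes (median 0.73, 7 higher, Tie1 at least 2.14) lay in the same direction. Thymocyte genes (median -2.99) and T cell genes (median -1.79) lay in the other, 11 of 12 and 13 of 21 at least 2-fold lower, and it was the KO-labelled control array that stood apart in them. In all, 2554 of 26244 genes differed by at least 2-fold (1210 higher, 1344 lower), and 639 with normexp background correction (333 higher, 306 lower).

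How far the responses of the genotypes resembled each other was measured across genes, which are not independent replicates. The responses share no array. In the table they correlated at a Pearson r of 0.160 (Spearman 0.303), and 248 genes were at least 2-fold different in the same direction in both pairs, 200 of them higher against 22.4 for independent lists and 48 lower against 4.83, while 145 went opposite ways. Among the genes selected by a mean response of 2-fold or more, the median of the KO-labelled response minus the WT-labelled one was 0.53 for the higher and -0.073 for the lower genes. In the scanner files the correlation was 0.234 (Spearman 0.325), 258 genes were higher in both against 29.1, 176 lower in both against 25.8 and 204 opposite, and the median differences were 1.16 and -1.14. The genotype differences of the control and challenged arrays correlated at 0.411 in the table (Spearman 0.382) and 0.211 in the scanner files (Spearman 0.263). In the table, 200 genes were higher in both against 11.7 for independent lists, 456 lower in both against 33.8, and 127 opposite. For opposite genes within a source, the number for independent lists was not computed. Whether they too were in excess is therefore not shown here, and the excess in the same direction alone does not measure a shared response.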

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

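Several tests were chosen only after the results were seen. They were those of column order, mismatched probes, airway epithelium with little of its wall, exchanged labels and mature T cells. The allowances for spread in all tests were also chosen then. Standard errors given with list medians, or with their difference, were computed as for means across the member genes of the lists. They treat these genes as independent, which they are not, and measure no variation between arrays or pools.

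These results were singled out because the challenged array was higher than its control in 1 genotype and lower in the other. For genes this meant at least 2-fold in both pairs, among ranked genes and printed list members above background on all 4 arrays. For lists it meant medians of opposite sign, both outside the central 95% of random lists. Each is given as the KO-labelled response minus the WT-labelled response on the log2 scale, with both responses, and rests on 1 array per group. Those from the scanner files were Rxfp3 (-4.32, from 1.74 in the WT-labelled and -2.58 in the KO-labelled pair), Oxct2b (-4.06, from 1.65 and -2.41), Defb26 (-3.48, from 1.56 and -1.93), Neurod2 (-3.39, from 1.64 and -1.75), Dnajb8 (-3.23, from 1.19 and -2.04), Dsg1c (-3.18, from 1.33 and -1.85), Kif12 (-3.16, from 1.36 and -1.81), Angptl7 (-2.80, from 1.07 and -1.73), Marco (3.95, from -2.01 and 1.94), Cd5l (3.79, from -1.85 and 1.94) and Ccl24 (2.72, from -1.35 and 1.37). The scanner lists were B and plasma cell genes (1.15, from -1.0 and 0.13) and immediate early genes (0.81, from -0.20 and 0.52). In the value table they were Awat1 (-4.73, from 1.24 and -3.48), Dppa4 (-3.51, from 1.70 and -1.81) and Cxcl3 (-2.76, from 1.32 and -1.44), and the lists of heart muscle genes (-1.13, from 0.50 and -0.61), fat cell genes (-0.90, from 0.35 and -0.35) and red blood cell genes (0.39, from -0.14 and 0.23). None of these differences was tested.

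The first pattern is that the value table and the scanner files hold different values under the same sample names. Another order of columns or another normalization is argued against by the highest correlation of probe deviations over the 16 pairs of a scanner array and a table column, 0.110, and a mismatch of probes is argued against by the 10 spike-in probes, whose levels correlated at 0.997. Scanner arrays mostly of large airway epithelium with little of the wall below it may account for the levels: all 13 measured genes of an airway basal and squamous epithelium list were higher in the scanner files (median 5.01, 2 standard errors 1.63, upper end of the 95% range of random lists 0.966), and the smooth muscle and matrix list was at -3.80. The most abundant genes of that list were Krt15 (6.23 against -3.94 in the table) and Aqp3 (5.53 against -2.10), 9 of the 13 genes were above background in all 4 table columns, and 1, Krt15, is also a club cell gene of the planned lists. The level of Krt5 (5.57 against -4.05) had been seen before the list was written. The matrix median was known too, so this outcome describes the levels and cannot decide the explanation. Of 12 cartilage genes, 9 were higher in the scanner files. More large airway with its wall cannot be told apart, since the cartilage median of 1.24 lies within its spread (0.890) of the upper end of random lists (1.58), and no biological explanation was tested, as genotype and treatment are the same in both sources and the labels give whole lung throughout.

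The second pattern is that Pla2g3 was higher in the arrays labelled knockout and is 1 of 17 genes that differed between genotypes in both sources. A differing interval of chromosome 8, considered because 6 of the 17 lie there, cannot be told apart: between the outermost of them, those 6 left out, the share of genes different in both treatments was 1.17 times that elsewhere in the table (8 of 302, exact Clopper-Pearson upper end 2.27 times) and 2.73 times in the scanner files (13 of 307, upper end 4.59 times), where a ratio of 3 in both was needed. The upper end in the table lies under 3, but this share leaves out the genes that make up the pattern, so it excludes nothing, and counting them (upper end 3.30 times) uses genes that the interval was drawn from. Of the 6 genes, Lpcat2 starts at 95443101, while the others start between 72265659 and 74948462. Of the other named genes different in both treatments, Tmem59l, Lrrc25 and Bst2 lay in that narrower stretch in the table, and Sall1 and Gm3134 outside. In the scanner files Hapln4, Haus8, Colgalt1 and Hsh2d lay in it. Gm6360, Gm9725, Inpp4b, Ptger1, Misp3, Podnl1 and Gadd45gip1 lay outside. The narrower stretch was seen only after the values and was not tested. DNA that came with the knockout allele cannot be told apart either, since within 10 Mb of Pla2g3 the share was 1.92 times that elsewhere in the table (5 of 114, 4.39%, exact interval 1.44% to 9.94%) and 2.12 times in the scanner files (4 of 118), too few genes to reach or exclude a ratio of 3. Exchanged labels cannot be told apart. Over both treatments and both sources, the lowest KO-labelled minus WT-labelled difference was 3.19 for the Pla2g3 probe used and 2.12 for the other probe. Where these probes lie against the deleted part is not given. An effect of the Pla2g3 deletion itself stays open and untested, with 1 pool per group.

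The third pattern is that thymocyte genes were higher in the KO-labelled control array of the scanner files, by a median of 4.09, and not in that of the table, where the median was -0.46. More mature T cells cannot be told apart as the whole source: the thymocyte median exceeded the T cell median of 2.65 by 1.44 (2 standard errors 1.07), where at most 1 was allowed, and the 5 genes of immature thymocytes (median 5.44), all on planned lists, were picked after their values were seen. Thymus tissue in that pool cannot be told apart: the thymic epithelium list had a median of 0.150 (2 standard errors 0.426) beside an upper end of 0.151 for random lists, and the cartilage list, of another tissue, one of 0.50 (2 standard errors 0.496, upper end 0.186). The most abundant of the 12 thymic epithelium genes, Cldn3 (5.38 in the WT-labelled and 5.29 in the KO-labelled control) and Ctsl (4.61 and 4.66), have a baseline that would hide a small share, while Foxn1 (2.01, from a level near the floor), Pax1 (1.05), Ccl25 (0.89) and Prss16 (0.85) were higher in the KO-labelled control and Tbata (-0.54), Ly75 (-0.41), Dll4 (-0.19) and Il7 (-0.14) lower. A biological effect of genotype stays open and untested, with 1 pool per group.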

How the results depend on the processing

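The alternatives were fixed before the data were examined, except that those on the value table, on averaged 2-fold counts, on the agreement of genotype differences and on genes shared by both sources were chosen after the results were seen. Values are in the order WT-labelled response, KO-labelled response, genotype difference in controls, genotype difference after challenge, difference of responses, averaged challenge effect and averaged genotype effect, as counts of genes at least 2-fold different, unless said otherwise. The cause of these changes was not tested, apart from those that follow from a looser or stricter rule. Quantile normalization, median scaling, the mean of a gene's probes and robust eBayes left every count within 1.5 times, and the median difference of all genes stayed within 0.1 of 0 in each setting. Within a source no named gene changed direction under any setting, and 1 list median near 0 did, that of the phospholipase A2 family for the averaged challenge effect in the table. It was -0.0081, 0.069 with the mean of a gene's probes, and 0.027 both with only genes above background on all 4 arrays and with no filter. Of the named genes and list medians under settings within a source, 580 values in the scanner files and 702 in the table stayed close to the main one, and 104 and 15 moved further. The genes shared by both sources numbered 14 to 17 for genotype and 15 to 20 for challenge over 4 alternatives each. Of 80 named genes in each source, 69 or more of the scanner files and 71 or more of the table were named again under each setting within the source except normexp. Counts of single pairs are limited by dim probes, since requiring signal over background on all arrays removed many of them. No paired analysis was possible because each group has 1 array. No array could be left out for the same reason.

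With normexp background correction the scanner counts were 190 (133 higher, 57 lower, against 621 and 524), 715 (436 and 279, against 1115 and 1106), 468 (359 and 109, against 917 and 609), 498 (354 and 144, against 1078 and 1023), 639 (333 and 306, against 1210 and 1344), 349 (229 and 120, against 745 and 621) and 334 (273 and 61, against 917 and 583). Limma passed 1 gene for challenge, Cxcl5 (adjusted p = 0.0237), the responses correlated at 0.470 and the genotype differences at 0.371, and 40 of the 80 named genes were named again.

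With only genes above background on all 4 arrays the scanner counts were 491, 1274, 874, 1067, 1286, 573 and 659, with correlations of 0.401 for responses and 0.350 for genotype differences. The table counts were 334, 581, 718, 749, 552, 275 and 613, with 270 passing limma for genotype (102 higher, 168 lower) and correlations of 0.394 and 0.661. At 1.5-fold the scanner counts were 2764, 4788, 3433, 4327, 4943, 3145 and 3415, and the table counts 1849, 2697, 2818, 2902, 3266, 1919 and 2511. At 3-fold they were 518, 1180, 699, 1025, 1366, 593 and 530 in the scanner files and 479, 551, 729, 842, 840, 380 and 672 in the table. A difference over 3 times the spot error left 737 scanner genes for the WT-labelled response and 1415 for the difference of responses. With no filter the table gave 1531, 1913 and 2025 genes for the first 3 comparisons and 2585 for the difference of responses. With a trend of variance, limma passed 1 scanner gene for challenge. In the table it passed 118 genes for challenge (100 higher, 18 lower) and 1047 for genotype (413 higher, 634 lower).

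With the value table in place of the scanner files, the counts furthest from the scanner ones were 1160 for the KO-labelled response, 1569 for the difference of responses and 848 for the averaged challenge effect. The responses correlated at 0.160 and the genotype differences at 0.411, and 5 of the 80 named genes were named again. The split into higher and lower was 604 and 281 for the WT-labelled response, 820 and 340 for the KO-labelled response, 487 and 824 for genotype in controls, 535 and 936 after challenge, 587 and 261 for the averaged challenge effect and 453 and 813 for the averaged genotype effect.

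Of the medians and genes named for the scanner files, 74 values had the opposite sign in the table. Among list medians of genotype after challenge they were T cell genes (-0.56, scanner 0.93), acute phase genes (-0.053, scanner 0.76), chemokines (-0.29, scanner 1.83), dendritic cell genes (-0.56, scanner 0.86), immediate early genes (-0.033, scanner 0.61), neutrophil genes (-0.062, scanner 1.30), thymocyte genes (-0.15, scanner 1.11) and type 2 genes (-0.032, scanner 0.83). For genotype in controls they were T cell genes (-0.79, scanner 2.65), cell cycle genes (-0.37, scanner 1.13), endothelial genes (0.11, scanner -0.60) and thymocyte genes (-0.46, scanner 4.09). For the difference of responses they were T cell genes (0.10, scanner -1.79), endothelial genes (-0.029, scanner 0.73), immediate early genes (-0.037, scanner 0.81) and thymocyte genes (0.13, scanner -2.99). For the averaged challenge effect they were T cell genes (0.17, scanner -1.57), cell cycle genes (0.83, scanner -0.38), circadian clock genes (0.26, scanner -0.55), endothelial genes (-0.14, scanner 0.45) and interferon genes (-0.052, scanner 0.63). For the KO-labelled response they were thymocyte genes (0.10, scanner -3.42).

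The named genes of opposite sign are given with their table values. Of these 52 values 6 use arrays at background (Myl10, Col2a1, Pth, H2-T3 and both of Ptcra), so that their size is not measured. For genotype after challenge they were Acod1 (-0.97), Ccl17 (-1.17), Ccl22 (-1.09), Ccl7 (-0.52), Cxcl1 (-0.042), Cxcl2 (-0.27), Cxcl3 (-0.46), Cxcr2 (-0.27), Egr2 (-0.029), Gal3st2 (0.18), Il17a (-1.53), Il1b (-0.019), Il6 (-0.19), Mrgpra6 (-0.57), Rxfp3 (0.21), Slc26a4 (0.62) and Tslp (-0.086). For genotype in controls they were Cd8a (-0.48), Cd8b1 (-0.48), Cldn5 (0.094), Dcstamp (0.93), Dntt (-0.61), Lck (-0.55), Mmrn2 (0.030), Myl10 (-2.29), Serpina3n (0.35), Sh2d1a (-0.43), Slc26a4 (0.46), Tie1 (0.050), Top2a (-0.74) and Trat1 (-1.14). For the difference of responses they were Acod1 (-1.54), Cd5l (-0.83), Clec4e (-0.069), Col2a1 (1.47), Cxcl3 (-2.76), Dntt (0.82), Endou (0.0032), Fosl1 (-0.61), Il17a (-0.29), Ptcra (1.36), Tie1 (-0.10) and Tmem151b (0.52). For the averaged challenge effect they were Bcl11b (0.071), Cd3d (0.17), Dbp (1.94), H2-T3 (0.95), Ptcra (0.32), Pth (1.01), Sh2d1a (0.26), Slfn4 (-0.010) and Tmem151b (0.076).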

Other observations

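The comparisons of antigen receptor segments and of chromosomes were chosen after the values were seen, and the other lists given here, apart from thyroid and parathyroid genes, before the data were examined.

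In the value table, gene segments of immunoglobulins and T cell receptors were lower in the KO-labelled arrays. Of 270 segments 118 were at least 2-fold lower in both treatments and 0 were higher (43.7% in all, against 1.83% of other genes in either direction). Their median was -0.93 in controls and -1.08 after challenge, with -0.83 and -1.04 under quantile normalization and -0.87 and -1.05 under median scaling. Of 228 segments in the scanner files, 18 were at least 2-fold higher in both treatments and 1 was lower (8.33% in all, against 1.55% of other genes). As a set they differed little there, with a median of 0.056 in controls and 0.204 after challenge. Probes for segments share sequence, so they are not separate measurements. With these segments left out, genes different in the same direction in both treatments were most frequent on chromosome 14 in both sources, with 65 of 907 genes in the table (7.17%) and 33 of 935 in the scanner files (3.53%). Chromosome 12 followed in the table with 50 of 913 (5.48%), and chromosome 5 in the scanner files with 37 of 1434 (2.58%).

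Circadian clock genes differed after challenge in opposite directions in the sources. In the table their averaged median was 0.26 (0.46 in the WT-labelled and 0.16 in the KO-labelled pair), with Dbp at 1.94, Nr1d1 at 1.34, Nr1d2 at 1.26 and Per3 at 1.08. In limma's additive fit 8 of the 19 genes passed when adjusted over the list alone and 0 over all genes. The count within the list is conditional on its being picked for description after its values were seen. The averaged median of the scanner files was -0.55, with Dbp at -1.61. The time of day at which lungs were taken is not given in the sources used here. The phospholipase A2 family as a whole had an averaged challenge median of -0.0081 in the table (0.063 with arrays at background set to the floor), inside the range of random lists, but 3 of its 29 measured genes were at least 2-fold higher: Pla2g4c (2.98), Pla2g10 (1.74) and Pla2g4d (1.36, from 2.69 in the WT-labelled and 0.036 in the KO-labelled pair). The thyroid and parathyroid list was higher in the scanner files than in the table by a median of 1.44, under the upper end of the 95% range of random lists (1.80).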
